A study of Arabidopsis thaliana with 6 samples.

How the data were processed

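The series held 6 Affymetrix Arabidopsis ATH1 arrays, 3 from seedlings given the compound and 3 from seedlings given DMSO. Per the labels' protocols, seedlings grew in multi-well plates on half-strength Murashige and Skoog medium, RNA was purified on silica columns, and 100 ng was labelled with biotin by in vitro transcription from the 3' end. Group and replicate number were taken from the sample titles, which call the samples biological replicates.

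The deposited values were log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, sets all arrays to the same quantiles and summarises the probes of a probe set. The software and its version were not given in the sources used here. The array medians lay between 5.75 and 5.79. Because RMA forces the arrays to a common distribution, a shift of all transcripts at once would not show, and small values are compressed towards the background. The file gave no detection calls or background intensities, so values near the low end cannot be separated from background. The number of arrays limits the precision.

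The table held 22810 probe sets, of which 64 control probe sets were left out of all tests, and 22746 were tested. Names came from the platform annotation given with the values, updated through the NCBI gene table of the TAIR10.1 assembly. Of the tested probe sets, 13513 (59.4%) had 1 gene, 503 had several and 8730 were unnamed here. 13436 of the single-gene probe sets matched a locus tag by gene number. No gene was named from a probe set with several genes. The 13355 genes with a single-gene probe set were each represented by the one with the highest mean over the 6 arrays. A gene of a list was printed under its list symbol only where the gene table held that symbol. No genome was used, and no coordinates are given.

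Compound and DMSO were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment as the only term). Probe sets were called at a Benjamini-Hochberg adjusted p below 0.05 over the 22746, and counted again where the log2 fold change was also at least 1. Unless a sentence says otherwise, each adjusted p of a gene in the text is limma's over all tested probe sets. A log2 fold change is compound minus DMSO, with its moderated standard error.

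Whether the replicate numbers pair the samples was checked from the deviations of each array from its group mean, over all tested probe sets. Arrays with the same number correlated at 0.727, 0.728 and 0.743 across probe sets, which are not independent replicates, and arrays with different numbers at -0.275 to -0.426. Deviations from a group mean cancel out within the group, so the negative values follow from the positive ones and add no evidence. All 3 pairs exceeded 0.1, the limit set beforehand for calling the samples paired. The pairing comes from the numbers in the titles and from this check. The labels do not say what the arrays of a number shared. The fit with the replicate number as a block was therefore printed beside the main counts and beside each gene or list call it changed.

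Before the data were examined, 29 gene lists with 574 entries were written down, along with the tests, the alternatives and the rule for naming genes. Of the 574 entries, 94 could be measured here, 2 were dropped because their symbol belonged to another locus, and the rest had no single-gene probe set named here. The 3 lists on auxin response factors and receptors, on hypoxia and on xylem and phloem had no measured member and were not analysed here. The 14 lists with at least 3 measured genes were tested against all other genes with camera at a preset correlation of 0.01, with adjustment over the 14. Of the 3 list calls (lateral root formation, auxin conjugation and oxidation, senescence), 0 held with an estimated correlation. In that setting camera rests on the residual degrees of freedom of the fit (4, and 2 with the block), so few lists can pass. A call lost there can reflect this low power and does not by itself show correlation between members.

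The rule named the 12 largest rises and 12 largest falls among called single-gene probe sets whose groups did not overlap. From each list it took the 1 gene with the smallest p, or 3 or 4 genes where the list test called the list or 3 members were called. It also named 8 genes whatever their result, of which 2, GH3.3 and LBD29, had a single-gene probe set and the other 6 were not analysed here. A total of 52 genes were named this way. No named gene had more than 1 single-gene probe set. Further list members are named in the text to describe their lists, and these and all other genes outside the rule were picked after their values were seen. Added after the data were seen were a list of class III peroxidases and a list of 15 root-abundant genes, the latter chosen without looking at their values.

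RNA integrity was read from the difference between 3' and 5' probe sets of the actin, GAPDH and ubiquitin controls, with an exact two-sided permutation test. Alternatives were the replicate block, leaving out each array, median centring, a second quantile normalization, 2 filters on dim probe sets, a variance trend with robust moderation, array weights, an adjusted p threshold of 0.01, a test against a fold change of 1.2, counting genes, a gene level averaged over probe sets, an estimated correlation, and fry. Added after the data were seen were the block without each pair, the block with an estimated correlation, the replicate number as a random block, and the integrity measure without each array.

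The fits were tested on simulated arrays of 22746 probe sets, 200 of which were changed. Where the simulated replicates were paired, the fit without the block found 57% of the changes of 1 log2 unit and 97% of those of 2, with 0 false calls among 154. The fit with the block found 100% of both, with 24 false calls among 224, which is above the nominal 5%. Where they were not paired, the fit without the block found 77% and 97%, with 9 false calls among 183, and the fit with the block found 67% and 97%, with 13 among 177. Each case was 1 random draw, with noise independent between probe sets and variances taken from the fits, so these shares are rough. In the simulated list tests, between 3.5% and 4.5% of 200 unchanged lists had a p below 0.05, for simulated noise that was independent between genes.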

Results

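Transcript levels were measured in whole seedlings of Arabidopsis thaliana, ecotype Columbia, with the Affymetrix ATH1 expression array. Seedlings 7 days old received 5 µM of a synthetic compound, or the solvent dimethyl sulfoxide (DMSO) alone, and RNA was taken after 24 h. The compound is the amide of 2-(2,4-dichlorophenoxy)propanoic acid with an aniline that carries an isobutyrylamino and a methoxy group. Its dichlorophenoxy group is also part of the synthetic auxin 2,4-D. Each group held 3 biological replicates, and each replicate was a pool of seedlings from 24 wells sown with 5 seeds each. The values were log2 RMA expression values, with array medians between 5.75 and 5.79. The series title concerns auxin signalling and cell death driven by hydrogen peroxide from photorespiration. The single comparison the design allows, compound against DMSO, therefore asks which transcripts differ after 24 h with the compound, and whether auxin-response, photorespiratory and oxidative-stress genes are among them.

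After 24 h with the compound, 3 of 5 measured genes of lateral root formation, 2 of 6 of auxin conjugation and oxidation and 1 of 7 Aux/IAA genes rose, while both measured root hair markers fell. With the replicate number as a block these counts were the same, except that 3 of the 6 genes of auxin conjugation and oxidation rose and 1 fell. IAA29, which encodes an Aux/IAA repressor of auxin response, was 4.34-fold higher. The lateral root regulators LBD29 and LBD16 were 3.84-fold and 3.06-fold higher. GH3.5 and GH3.1, which encode enzymes that conjugate auxin to amino acids, were 3.58-fold and, as measured, 2.54-fold higher. In the other direction, the class III peroxidase gene AT1G34510 was 10.3-fold lower as measured, and the root hair expansin gene EXPA7 was 4.28-fold lower.

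In total 78 of 22746 probe sets changed at an adjusted p below 0.05 (limma, Benjamini-Hochberg), 27 up and 51 down, and 70 of them changed at least 2-fold, 26 up and 44 down. Of the 78, 38 had 1 named gene (17 up, 21 down), 2 had several and 38 were unnamed here. With the replicate number as a block, 865 probe sets changed (416 up, 449 down), 203 of them at least 2-fold (88 up, 115 down). Of the 865, 415 had 1 named gene (208 up, 207 down), 18 had several and 432 were unnamed here. All 78 were among the 865, with the same direction. In each of the 78 the 3 compound arrays lay wholly above or wholly below the 3 DMSO arrays. Over all probe sets, 2215 (9.74%) had non-overlapping groups, where chance gives 10% for arrays that vary independently of each other. In the 3 other splits of the arrays that also part every same-numbered pair, 3.08%, 4.33% and 4.88% of the probe sets did not overlap. In the fit without the block, the number of calls rested on single arrays. Each fit without 1 array breaks a pair and has 3 in place of 4 residual degrees of freedom. Counts with the block and without a whole pair are given further below. Without DMSO replicate 2 limma called 40 probe sets, without DMSO replicate 3 it called 1, and without compound replicate 1, 2 or 3 it called 0, with 1022, 1049 and 1047 probe sets at an unadjusted p below 0.05. Without DMSO replicate 1 the total was 76, with 15 up in place of 27. All 78 kept their direction and an unadjusted p below 0.05 whichever array was left out.

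Of 94 measured genes on the lists fixed beforehand, 6 rose and 2 fell, and with the replicate block 13 rose and 4 fell. The 6 were genes of auxin response, auxin conjugation and lateral root formation. Of 7 measured Aux/IAA genes, out of 28 on the list, 1 rose and 6 did not pass the test. The 7 were IAA18, IAA20, IAA29, IAA30, IAA31, IAA33 and IAA34. IAA19 had no single-gene probe set here, and most of the list was not read, so these counts do not describe the family. The riser was IAA29, at 6.95 ± 0.03 (SD, n = 3) with the compound and 4.83 ± 0.18 (SD, n = 3) with DMSO, a log2 fold change of 2.12 (SE 0.11, adjusted p = 0.0142). Adjusted over the list alone, 2 Aux/IAA genes rose, the second being IAA30 (log2 fold change 0.47, SE 0.13), a pick made after its value was seen, and with the block 2 rose and 2 fell. The other 5 lay between -0.28 and 0.18. Among them IAA20, IAA31, IAA33 and IAA34 had means of 3.55 to 4.09 in both groups, near background, where a change can go unseen. The list test missed the threshold (camera, adjusted p = 0.174). It passed, upward, where only probe sets with a mean of at least 4 on the log2 scale were kept, which left 4 of the 7 genes (adjusted p = 0.000103). The adjusted p was 0.438 with an estimated correlation over all probe sets, and ranged up to 0.502 over the alternatives.

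Of 6 measured genes of auxin conjugation and oxidation, 2 rose and 4 did not pass the test. GH3.5 stood at 10.75 ± 0.09 (SD, n = 3) with the compound against 8.91 ± 0.25 with DMSO (log2 fold change 1.84, SE 0.14, adjusted p = 0.0147). GH3.1 had a log2 fold change of 1.34 (SE 0.10, adjusted p = 0.0147), with a DMSO mean of 4.04, near the lower quartile of the DMSO arrays (3.95 to 4.06), so the measured difference can understate the rise. With all arrays, GH3.3 had the widest difference of any named gene as measured, 3.82 on the log2 scale (SE 0.67), with all 3 compound arrays above all DMSO arrays. It ranged from 3.18 to 4.59 over the alternatives and AT1G34510 from -3.67 to -3.17, so this rank was not fixed. The DMSO values of GH3.3 were 6.18, 9.0 and 7.17. It missed the threshold without the block (adjusted p = 0.131) and passed it with the block (adjusted p = 0.00737) and without DMSO replicate 2 (adjusted p = 0.0387). AT1G14120, entered in the list as the auxin oxidase DAO2, was at -1.21 (SE 0.23; adjusted p = 0.187, and 0.0111 with the block). Adjusted over the list alone, 3 genes rose and 1 fell, both with and without the block. The list test gave a shift upward (camera, adjusted p = 3.82e-05), which was not kept with an estimated correlation (adjusted p = 0.267).

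**Figure D1:**
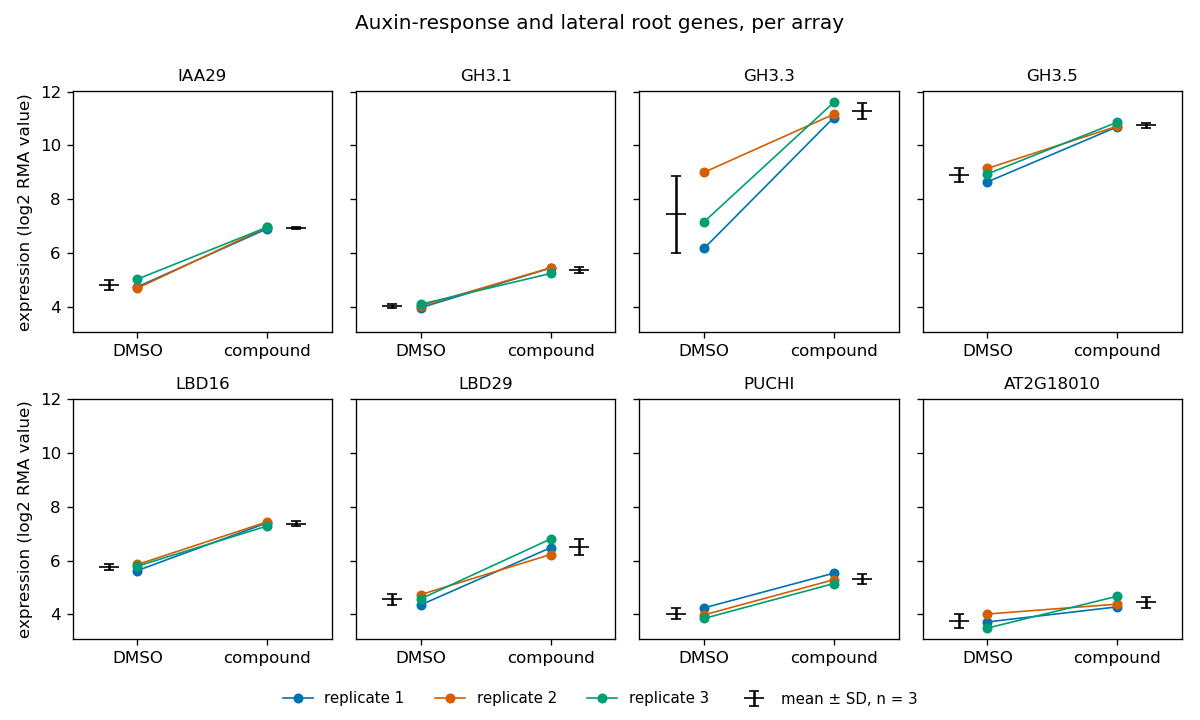
Log2 RMA values of 8 auxin-response and lateral root genes on each array, DMSO at the left and compound at the right of each panel. Lines join arrays with the same replicate number, and black bars are group means ± SD (n = 3). All 3 compound arrays lie above all 3 DMSO arrays in each panel, and GH3.3 has the widest DMSO spread, from 6.18 to 9.0.

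Of 5 measured genes on the list of lateral root formation, 3 rose and 2 did not pass the test. LBD29 and LBD16, transcription factor genes that act early in lateral root founder cells, had log2 fold changes of 1.94 (SE 0.17, adjusted p = 0.0173) and 1.61 (SE 0.10, adjusted p = 0.0147). PUCHI, an AP2-type transcription factor gene of lateral root primordia, had a log2 fold change of 1.3 (SE 0.15, adjusted p = 0.0313), with a DMSO mean of 4.03, also near that quartile, so the same limit holds. LHW was at 0.13 (SE 0.12) and ACR4 at 0.03 (SE 0.18). The same 3 genes rose when adjusted over the list alone. The list shifted upward (camera, adjusted p = 8.58e-09). With an estimated correlation the adjusted p was 0.0868. The 1 measured SAUR gene, AT2G18010, had a log2 fold change of 0.70 (SE 0.17, adjusted p = 0.325). Adjustment over a list of 1 gene changes nothing and leaves the unadjusted p of limma, 0.00485. Its DMSO mean of 3.74 lay below the lower quartile of the DMSO arrays. Auxin transport was measured by WAG2 alone, at 0.70 (SE 0.44, adjusted p = 0.999), and auxin biosynthesis by YUC2, YUC4 and YUC6, which lay between 0.03 and 0.16 and did not pass the test.

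Beyond these, the 12 largest rises among called single-gene probe sets took in genes of other functions. AT1G64405 had a log2 fold change of 2.15 (SE 0.26, adjusted p = 0.0406). CLE44, the precursor of a peptide signal in vascular development, had one of 1.63 (SE 0.20, adjusted p = 0.0406). AT1G67750, a pectate lyase gene, was 3.26-fold higher, and AT3G25290, of an auxin-responsive protein family, was 3.34-fold higher. AT1G30760, of the berberine bridge enzyme family, was 3.03-fold higher, PR-1-LIKE was 3.09-fold higher and AT1G73120 was 2.77-fold higher. The adjusted p of these last 5 ran from 0.0177 to 0.0458. Of the 12 rises, limma still called 6 without DMSO replicate 1, 7 without DMSO replicate 2, 1 (IAA29) without DMSO replicate 3 and 0 without any 1 compound array, where it called no probe set at all. Their log2 fold changes in these fits were 0.872 to 1.15 times those with all arrays (IAA29 2.05 to 2.22, LBD16 1.55 to 1.66), and all 12 stayed at least 2-fold. The lowest adjusted p was 0.0941, 0.0514 and 0.0592 without compound replicate 1, 2 and 3.

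The 12 largest falls among called single-gene probe sets included 4 class III peroxidase genes, a family outside the lists fixed beforehand. Of its 55 measured genes, 4 fell and 0 rose without the block, and 10 fell and 6 rose with it. AT1G34510 fell from 7.64 ± 0.53 to 4.28 ± 0.23 (SD, n = 3), a log2 fold change of -3.36 (SE 0.27, adjusted p = 0.0147). AT3G49960, AT4G26010 and AT1G30870 had log2 fold changes of -2.71 (SE 0.21), -2.70 (SE 0.26) and -2.07 (SE 0.17), with adjusted p of 0.0147, 0.0203 and 0.0149. XTH26, a xyloglucan-modifying gene, had a log2 fold change of -2.67 (SE 0.30, adjusted p = 0.0318). The compound means of XTH26 (3.92) and AT1G34510 lay below and near the lower quartile of the compound arrays (4.01 to 4.02), where values cannot be separated from background, so the measured differences can understate these falls. AT5G04960, a pectin methylesterase gene, had one of -2.46 (SE 0.31, adjusted p = 0.0461). AT5G06630, an extensin-like gene, was 2.93-fold lower, and AT4G13580, a dirigent-like gene, was 3.92-fold lower. AT1G30750 was 3.41-fold lower and the protein kinase gene AT5G65530 was 2.39-fold lower.

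Both measured root hair markers fell. EXPA7 had a log2 fold change of -2.10 (SE 0.26, adjusted p = 0.042) and EXPA18 one of -1.81 (SE 0.20, adjusted p = 0.0266). With 2 members the list was too small for the list test. The 1 measured gene of the root tissue markers, PYK10, was at -0.10 (SE 0.12, adjusted p = 0.999). A set of 15 root-abundant genes, put together after the data were seen, had a median log2 fold change of -0.57, with none called without the block and 5 called down with it. The difference between 3' and 5' control probe sets, a measure of RNA integrity, was 2.64 on the log2 scale with the compound and 2.62 with DMSO for actin, 1.02 and 1.2 for GAPDH, and 1.52 and 1.58 for ubiquitin. Exact two-sided permutation tests gave p = 1, 0.2 and 0.7 (adjusted 1, 0.6 and 1), where 0.1 was the smallest possible. Of the 12 largest falls, EXPA7 and EXPA18 included, limma still called 11 without DMSO replicate 1, 5 without DMSO replicate 2, and 0 without DMSO replicate 3 or any 1 compound array. Without DMSO replicate 3, 1000 probe sets had an unadjusted p below 0.05. The log2 fold changes of the 12 in these fits were 0.885 to 1.16 times those with all arrays (EXPA7 -2.40 to -1.88, EXPA18 -2.0 to -1.60), and all 12 stayed at least 2-fold.

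**Figure D2:**
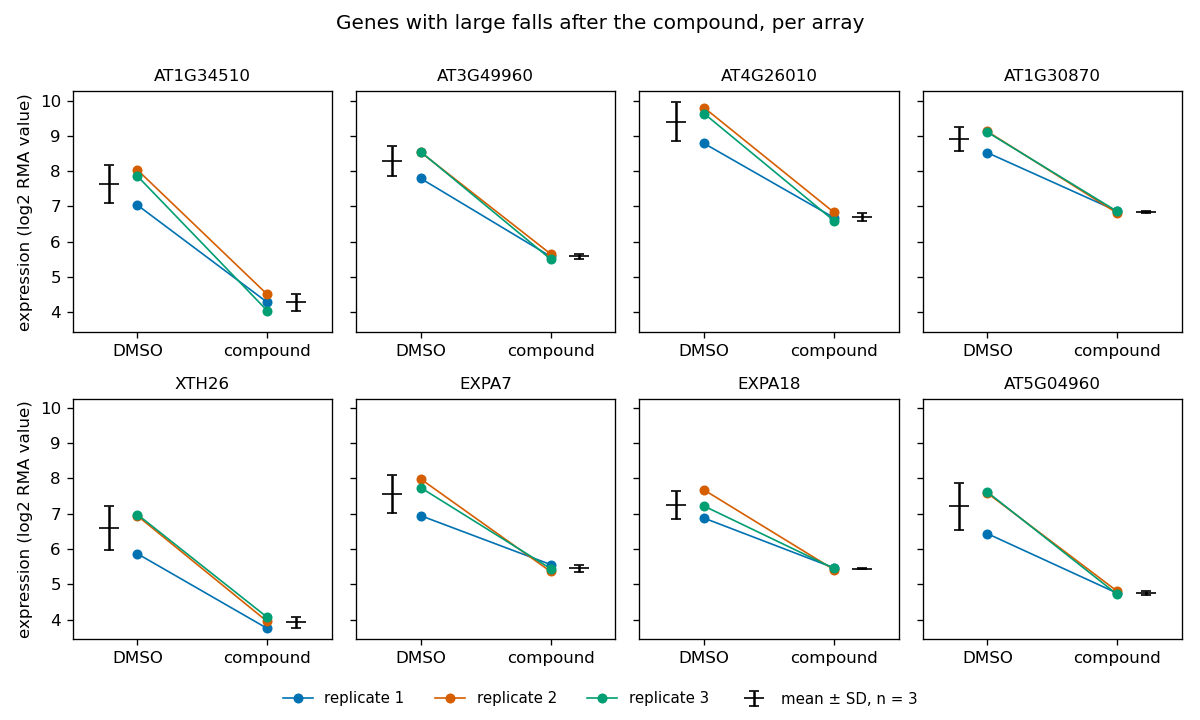
Log2 RMA values of 8 genes with large falls on each array, DMSO at the left and compound at the right of each panel. Lines join arrays with the same replicate number, and black bars are group means ± SD (n = 3). All compound arrays lie below all DMSO arrays, and the DMSO value of replicate 1 is the lowest of the DMSO values in each panel.

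None of the 11 measured genes on the list of expansins and XTH, which act in wall loosening, passed the test without the block, and 3 rose with it. EXPA7, EXPA18 and XTH26, which fell, belong to the same families but are outside this list. Of the 11, 8 had higher and 3 lower means with the compound. EXPA4 had a log2 fold change of 1.71 (SE 0.28; adjusted p = 0.109, and 0.000551 with the block). XTH19 and XTH18, 2 xyloglucan endotransglucosylase/hydrolase genes picked after their values were seen, had log2 fold changes of 1.47 and 0.74, with adjusted p of 0.000551 and 0.029 with the block. EXPA8 and XTH16 were at -0.70 (SE 0.49) and -0.70 (SE 0.46). Adjusted over the list alone, 2 genes rose without the block, and 5 rose and 1 fell with it. The list test missed the threshold without the block (camera, adjusted p = 0.0509) and passed it, upward, with the block (adjusted p = 0.00702). The adjusted p was 0.438 with an estimated correlation, and 0.394 with the block as well, so the call was not kept in that test of few degrees of freedom. At the preset correlation the list also passed without DMSO replicate 2 (adjusted p = 0.00776), compound replicate 1 (0.0287) and compound replicate 3 (0.0283), and with each array centred on its median (0.0484).

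The measured photorespiratory and antioxidant genes, 6 of 23 and 3 of 17 on their lists, showed small differences. CAT2 and GLO1 had no single-gene probe set here, so most of both lists was not read. None of the 6 measured photorespiration genes passed the test, and their median log2 fold change was -0.08 (camera, adjusted p = 0.232). AT1G80380, which encodes glycerate kinase, was at -0.47 (SE 0.26; adjusted p = 0.999) and fell with the block (adjusted p = 0.0286), also when adjusted over the list alone. Its call over all probe sets was not kept with the replicate number as a random block. The other 5, which included AT1G11860 of the glycine decarboxylase complex, lay between -0.19 and 0.04. Of 3 measured antioxidant genes none passed without the block, and the stromal ascorbate peroxidase gene SAPX, at 0.48 (SE 0.15; adjusted p = 0.576), rose with it (adjusted p = 0.0169). Adjusted over the list alone SAPX also rose without the block. TAPX and GR1 were at -0.13 (SE 0.22) and 0.06 (SE 0.31). The list test gave an adjusted p of 0.376.

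None of 7 measured oxidative stress markers passed the test with or without the block, or adjusted over the list alone. ZAT10, a stress-induced zinc finger gene, was at -0.03 (SE 0.17), AT1G19020 at 0.34 (SE 0.64) and AT2G41730 at -0.32 (SE 0.23). AT1G57630 was at 0.07. The standard errors of AT1G19020 and AT1G57630 were 0.64 each without the block and 0.13 and 0.11 with it, where the adjusted p were 0.279 and 0.83. The list test gave an adjusted p of 0.349. The 1 measured heat shock gene, ATHSP22.0, was at 0.03 (SE 0.12, adjusted p = 0.999). Its means of 3.95 with the compound and 3.92 with DMSO cannot be separated from background.

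Of 10 measured genes of xenobiotic detoxification, none passed without the block and 1 rose with it. That gene was AER, which encodes an alkenal reductase, with a log2 fold change of 0.51. Without the block its SE was 0.30 and its adjusted p 0.999, and with the block they were 0.099 and 0.0414. AT2G04050, a MATE-type transporter gene, was at 0.29 (SE 0.09, adjusted p = 0.599). Adjusted over the list alone, 0 genes rose without the block and 3 with it. The list test gave an adjusted p of 0.0835 without the block and 0.0408, upward, with it, and 0.00461 without compound replicate 3. The adjusted p with an estimated correlation was 0.438, and 0.394 with the block as well.

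The senescence list, with 4 measured members, shifted upward (camera, adjusted p = 0.0479), and with an estimated correlation the adjusted p was 0.438. No member passed on its own without the block. SAG29, which encodes a sugar transporter, was at 0.56 (SE 0.12; adjusted p = 0.254) and rose with the block (adjusted p = 0.029). WRKY6 and WRKY53, transcription factor genes, were at 0.42 (SE 0.33) and 0.37 (SE 0.26), and SAG101 at 0.01 (SE 0.19). Adjusted over the list alone, 1 gene rose without the block and 2 with it. The list call ended without DMSO replicate 1 (adjusted p = 0.434), DMSO replicate 3 (0.0652) and compound replicate 2 (0.243).

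**Figure D3:**
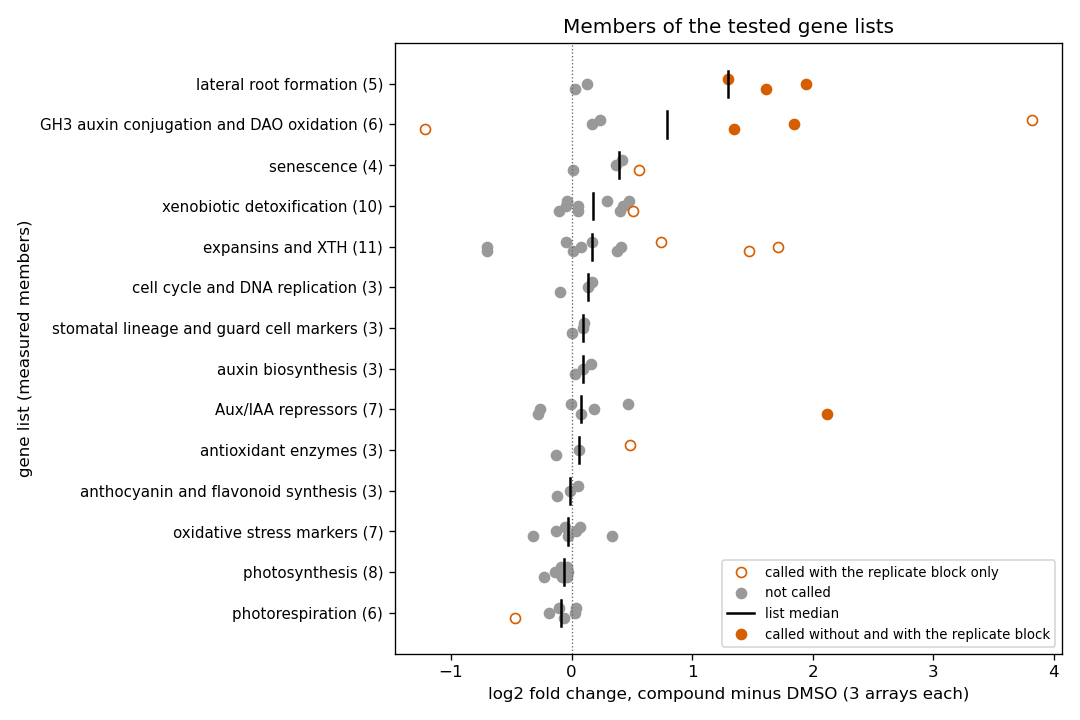
Log2 fold change (compound minus DMSO, 3 arrays each) of each measured member of the 14 tested gene lists, with the number of measured members in brackets. Filled orange points passed the test with and without the replicate block, open points only with it, grey points in neither, and black bars mark list medians. Lateral root formation has the highest median, 1.3, and photorespiration the lowest, -0.08.

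All 8 measured photosynthesis genes had lower means with the compound, and after a second quantile normalization 7 of 8 did. The widest difference was that of LHCB4.2 (-0.23, SE 0.12, adjusted p = 0.999). None passed the test, and the list missed the threshold (camera, adjusted p = 0.0509, and 0.0674 with the block). It passed, downward, without DMSO replicate 3 (adjusted p = 0.0251), without compound replicate 1 (0.0175) and with each array centred on its median (0.0484). With an estimated correlation the adjusted p was 0.532, and 0.394 with the block as well. Cell cycle and DNA replication was measured by MCM7, AUR1 and AUR2, at 0.14 (SE 0.15), 0.17 (SE 0.18) and -0.09 (SE 0.23), and the list test gave an adjusted p of 0.596. Anthocyanin and flavonoid synthesis, with UF3GT at -0.12 (SE 0.14), and the stomatal lineage, with FAMA at 0.10 (SE 0.24), had 3 measured genes each, none of them called. Their list tests gave adjusted p of 0.691 and 0.763, and auxin biosynthesis gave 0.361.

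Other hormone and timing lists were too thinly measured for a list test, and none of their genes passed the test with or without the block. For cytokinin, ARR15 was at -0.15 (SE 0.12) and ARR16 at -0.20 (SE 0.34). For jasmonate, THI2.1 was at -0.04 (SE 0.10) and PDF1.2 at 0.00 (SE 0.10). The ethylene factor gene EIN3 was at 0.01 (SE 0.16), the abscisic acid-responsive COR15A at 0.06 (SE 0.10) and the salicylic acid-responsive GRX480 at -0.14 (SE 0.09). The clock gene GI was at -0.09 (SE 0.33), and the shoot meristem gene CLV3 at -0.01 (SE 0.09). THI2.1, CLV3 and COR15A had means of 3.47 to 3.91 in both groups, below the lower quartile of every array (3.95 to 4.06). The means of ARR15, PDF1.2 and GRX480 lay near that quartile. Such values cannot be separated from background, so a change in these dim genes can go unseen. Their small standard errors therefore do not show that these genes were unchanged. The precision of all values in this paragraph was limited by the number of arrays and depended on the fit. The standard error of GI was 0.08 with the block and that of ARR16 0.09, and the median standard error over all probe sets was 0.125 without the block and 0.0835 with it.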

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

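The block without a pair, the block with an estimated correlation, the random block and the integrity measure without single arrays were chosen after seeing the data. All other alternatives were planned, and all were run. No result changed direction while called under any alternative. With the replicate block 865 probe sets changed (416 up, 449 down), 203 at least 2-fold (88 up, 115 down). Left without a pair, the block called 516 (204 up, 312 down; at least 2-fold 214, 77 up, 137 down) without pair 1, 743 (406 up, 337 down; 211, 112 up, 99 down) without pair 2 and 205 (101 up, 104 down; 147, 73 up, 74 down) without pair 3. The random block called 491 (216 up, 275 down; 168, 64 up, 104 down). The paired arrays share variation that the block removes, and the median standard error fell from 0.125 to 0.0835. Besides the counts, the block brought in the lists of expansins and XTH (0.00702) and of xenobiotic detoxification (0.0408) and 6 of the 52 named genes, and it changed no other call among these results. Both lists were at an adjusted p of 0.438 with an estimated correlation, and at 0.394 with the block as well.

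Leaving out single arrays moved the count between 0 and 76 (up 0 to 22, down 0 to 61), and at least 2-fold between 0 and 75 (up 0 to 21, down 0 to 61). Each such fit has fewer arrays and 3 in place of 4 residual degrees of freedom. The adjusted p of the lists ranged from 0.00103 to 0.434 for senescence, 0.00776 to 0.219 for expansins and XTH, 0.0175 to 0.39 for photosynthesis and 0.00461 to 0.344 for xenobiotic detoxification. The integrity difference, -0.07 with all arrays, ranged from -0.15 to 0.01. At an adjusted p of 0.01 limma called 0 probe sets (0 up, 0 down), with 1220 at an unadjusted p below 0.05 and 277 called with the block. Against a fold change of 1.2 it called 50 (13 up). Counting genes gave 38 (17 up, 21 down; at least 2-fold 34, 17 up, 17 down), since probe sets that were unnamed or had several genes were not counted.

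Median centring brought expansins and XTH (0.0484) and photosynthesis (0.0484) under the threshold, and the variance trend brought expansins and XTH (0.0448). The adjusted p of these lists was 0.438 and 0.532 with an estimated correlation. The filter at log2 of 4, which left 17105 probe sets, gave 0.000103 for Aux/IAA, 0.0187 for expansins and XTH and 0.0359 for xenobiotic detoxification. With an estimated correlation over all probe sets the adjusted p was 0.438 for each of these 3 lists. The filter leaves out the dimmest list members. Array weights gave 0.0879 for senescence. With an estimated correlation the adjusted p was 0.267 for auxin conjugation and oxidation, 0.0868 for lateral root formation and 0.438 for senescence. With the block as well it was 0.394, 0.394 and 0.411. Fry, which does not compare a list with other genes, gave 0.0142 for Aux/IAA and 0.372 for senescence. Calls lost with an estimated correlation can reflect the few residual degrees of freedom of that test. For the other list results whose alternative does not itself show why, the cause was not tested. The filter above the median brightness, which left 11373 probe sets, took some lists and named genes out of the tests. The lack of detection calls limits what can be said of dim probe sets.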

Other observations

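The tests of splits and of RNA integrity in the falling probe sets were chosen after the calls had been seen, as were both added gene lists, while the tests of the replicate numbers and of root tissue were fixed before their values were seen. The integrity test replaces one fixed beforehand, the same measure as a covariate, which left the median fall at -2.17 but moved all probe sets by a median of only 0.04 on the log2 scale and so decided nothing.

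Class III peroxidases, secreted enzymes that cross-link or loosen wall polymers, moved in both directions. Of 55 measured genes, 4 fell and 0 rose without the block, and 10 fell and 6 rose with it (limma; 7 and 3 of these by at least 2-fold). Besides the 4 largest falls, AT4G30170 was at -1.50 (SE 0.30), AT5G66390 at -1.43 (SE 0.20) and AT5G17820 at -1.41 (SE 0.20), with adjusted p of 0.000551, 0.00486 and 0.00359 with the block. In the opposite direction, AT2G18980 was at 1.83 (SE 0.37), AT4G08780 at 1.67 (SE 0.36) and AT4G36430 at 1.19 (SE 0.60), with adjusted p of 0.00883, 0.00118 and 0.00174 with the block. The standard errors are those of the fit without the block. There the adjusted p of AT4G30170, AT5G66390 and AT5G17820 were 0.201, 0.0629 and 0.0683. Those of AT2G18980, AT4G08780 and AT4G36430 were 0.207, 0.259 and 0.999. These genes were picked after their values were seen. Over the 55 genes the median log2 fold change was 0.03 and the mean -0.17. The family was looked at because members were seen among the largest falls, so that no test of the family as a whole on these arrays is given.

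Further genes outside the naming rule, picked after their values were seen, also changed. HAT2, a homeodomain-leucine zipper gene known as auxin-induced, rose (log2 fold change 1.14, adjusted p = 0.0361). Only with the block, the endoglucanase gene GH9C1 fell (log2 fold change -1.91, adjusted p = 0.00276, and 0.0551 without the block), while GH9C2 of the same family rose (1.42, adjusted p = 0.00116, and 0.621 without the block).

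Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many as 78 called probe sets, or as many as 70 called at least 2-fold, and the highest of the others was 0 for both. The real split had 1220 probe sets at an unadjusted p below 0.05. The 3 other splits that also part all 3 pairs had 72, 161 and 206, and those that part 1 pair had 1481 to 2318. With the replicate block, 1 of the 4 splits that part all pairs, again the real one, gave as many as 865, and the highest of the others was 0, with 285 to 697 at an unadjusted p below 0.05. Both sets of splits are too few for a share under 0.05.

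Arrays with the same replicate number deviated together, at correlations of 0.727 to 0.743 across probe sets. RNA integrity or labelling, as read by the 3' minus 5' controls, could produce this, but after regression on that measure the lowest of the 3 correlations was 0.230 and the highest 0.710, all above 0.1. That argues against it as the whole cause, and a part stays open. Background shared by dim probe sets is argued against by the probe sets brighter than the median, where the lowest correlation was 0.802. A shared day, plate or hybridization stays open and untested, since the labels give none, and no biological explanation was tested.

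The 44 probe sets that fell at least 2-fold had a median log2 fold change of -2.16 (SD 0.71). Less root tissue in the compound pools might lower root transcripts. The 15 root-abundant genes had a median of -0.57 (SD 0.56, from -1.67 to 0.27). That lay above the median of the falling probe sets by more than 1 SD, the outcome set beforehand for no such loss. The 44 were picked for their falls, however, so their median is extreme by selection. Of the 15, AT1G54020, AT3G29430 and AT5G47980 lay near background in both groups and could hardly fall. The comparison therefore does not decide it. At the preset correlation of 0.01, the root-abundant genes were lower than other genes (camera, p = 5.72e-11, adjusted over both added lists 1.14e-10). With an estimated correlation the adjusted p was 0.0534. Of these genes, 1 is also among the peroxidases. The list was put together after the falls were seen, so this test is no independent support. Less root tissue stays open as a cause. RNA integrity is argued against as a linear cause, since the 3' minus 5' measure differed by only -0.07 between groups, and within groups the 44 probe sets followed it with a median slope of 1.29 log2 units per unit of the measure (SD 1.05, from -0.60 to 2.98), where the median fall would need 29.8, or 14.5 at the widest difference without 1 array (-0.15). An effect of the compound on these genes stays open.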
